A study of Mus musculus with 15 samples.

How the data were processed

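Poly(A) RNA of mouse splenic B cells was sequenced in 15 libraries, 3 in each of 5 groups: naive CD43-negative cells, and GL7+ and CD138+ cells cultured with DMSO or 250 nM GSK-J4. Per the labels' protocols, RNA was extracted with a column kit and libraries were made from total RNA with a poly(A) selection kit. Groups and replicate numbers came from the labels, which call the CD138+ cells plasmablasts and the GL7+ cells activated B cells. The table's headers call the CD138+ cells by another abbreviation and match the labels by fraction, treatment and number. A CD138+ GSK-J4 column, numbered 4 in its header, matched the group and no single sample. Replicate 3 of that group in the labels had no column of its own. Whether this column holds that sample is not stated. It entered as a replicate of that group with no mouse of its own and is called replicate 4.

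The deposited values are RPKM per gene, per the file headers, for 21761 genes of the mm9 mouse genome. Per the submitters' processing notes, reads were aligned with TopHat2, and its version, the counting tool, the annotation, the strand setting and any filters are not given in the sources used here. Without a stated strand, overlapping and antisense genes cannot be told apart. The authors also deposited a gene length in bases, whose header and name point to summed exons. RPKM times length in kilobases summed to 1000000 in each library, so the values are relative to the reads assigned to these genes. Values worth up to 20 reads were whole multiples of 1 step per library, within 0.1 read in 100% of cases, which gave each library's depth, on average 9285987 reads. Symbols were those of the table. Of 21761 Entrez identifiers 21615 matched a RefSeq table of another mouse assembly, GRCm38.p6, which served for names only, so no coordinates are given. It restored 27 symbols that had been turned into dates, and 92 genes without a symbol kept their identifier. Immunoglobulin gene segments were not analysed here. Genes with near-identical copies are uncertain, since reads can be split between them: Mt1 and Mt2, Ly6c1 and Ly6c2, Bcl2a1a and Bcl2a1b, the globin genes, Oas1a, Mnda and Srp54a. So are 621 genes shorter than 200 bases.

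The design foresaw a test of counts if counts were given and limma if RPKM were given, and the RPKM branch was used. Genes with at least 1 RPKM in at least 3 libraries (10866 genes) were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3. All 15 libraries entered 1 fit with a mean per group and a trended variance, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts were GSK-J4 against DMSO in each fraction, the difference between these, CD138+ against GL7+ cells under DMSO, and each DMSO fraction against naive cells. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

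The 26 gene lists covered plasma cell, mature B cell and activated B cell genes, Polycomb complexes with the H3K27 demethylases, other JmjC demethylases, inhibitors of cyclin-dependent kinases and developmental Polycomb targets. Others held the unfolded protein response, ATF4 targets, S phase, G2 and M phase, MYC and ribosome biogenesis, NF-kB targets, interferon response, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, p53 targets, apoptosis regulators, the NRF2 and metal response and immediate early genes. The last 5 lists held markers of T, NK, myeloid, dendritic and erythroid or platelet cells. The 23 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists. "Adjusted over the list alone" means the Benjamini-Hochberg adjustment within 1 list.

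Genes named in the text followed a fixed rule. It took, in each GSK-J4 comparison, up to 8 genes per direction with the largest change among those past the threshold, with a mean of at least 5 RPKM in the higher group and no overlap between the groups' values (which chance alone gives in 10% of genes with 3 against 3). For the difference between fractions and for each comparison of cell states it took 5 per direction. It added 11 regulators in every comparison (Kdm6a, Kdm6b, Ezh2, Prdm1, Irf4, Xbp1, Sdc1, Pax5, Bach2, Bcl6 and 1 more) and up to 4 members of each described list with the smallest adjusted p. Of the genes that it took, 2 are not reported here. Genes named outside it are said to be so where they appear.

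Replicate numbers stood for the same mouse in every group, per the labels, so they pair the samples. Deviations from group means correlated with a median r of 0.09 between cultured samples of the same mouse (-0.03 to 0.19 over 15 pairs) and -0.03 between samples of different mice. A fit with the mouse as a block was the alternative to the unpaired fit, with the library without a mouse as a level of its own. That level fits this library exactly, so the block fit draws on only the other CD138+ GSK-J4 libraries. A call lost with the block in a comparison with that group can therefore reflect the loss of this library as well as the pairing. No replicates agreed within counting noise (chi-square per degree of freedom 1.84 to 8.59 over 15 replicate pairs). Correlations across genes of changes that share libraries were set beside the mean of 100 simulations of unchanged groups.

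The fit was tested on simulated reads with 200 genes changed at the real means and depths. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 72.7%, 86.9% and 94.3% in the CD138+ comparison (10931 genes in the fit), 71.8%, 92.4% and 95.2% in the GL7+ comparison (10934 genes) and 52.4%, 84.7% and 98.4% for the difference between them (10839 genes). For CD138+ against GL7+ cells the shares were 81%, 89.9% and 93.8% (10905 genes). They were 82.4%, 95.2% and 100% for GL7+ against naive cells (10804 genes) and 89.8%, 93.8% and 100% for CD138+ against naive cells (10792 genes). False calls were 2.2% to 7.91% of calls, and 0 of 20 unchanged lists passed. The simulated genes varied independently with 1 dispersion for all (0.00314), and the unchanged lists held genes drawn at random. The simulation therefore does not show how often lists pass falsely when their genes vary together. Alternatives were the block, a fit of only the contrast's libraries, no filter and a stricter one (at least 5 RPKM, 8542 genes), a pseudocount of 0.1, TMM and quantile scaling, library weights, a 2-fold minimum, a threshold of 0.01 and leaving out each library. Added later were the mouse as a random effect, voom on the recovered reads, thinning to 2636004 reads per library (10902 genes tested) and leaving out naive replicate 2 from the comparisons of cultured cells.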

Results

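RNA was sequenced from mouse B cells cultured with GSK-J4, an inhibitor of the enzymes KDM6A and KDM6B that remove the repressive histone mark H3K27me3, or with its solvent DMSO. Splenic CD43-negative B cells of female C57BL/6J mice were stimulated with LPS, IL-2 and IL-5 in the presence of 250 nM GSK-J4 or DMSO, and RNA was taken after 3 days. The cultured cells were enriched into a GL7+ fraction, a marker of activated B cells, and a CD138+ fraction, where CD138 (Sdc1) marks plasmablasts and plasma cells. Unstimulated CD43-negative cells served as the naive group. There were 5 groups of 3 libraries, and replicate numbers named the mouse of origin, except for 1 CD138+ GSK-J4 library that could not be tied to a mouse. Depth ran from 9806761 to 11519344 reads in GL7+ DMSO, from 9174688 to 12213703 in GL7+ GSK-J4, from 9676744 to 11636297 in CD138+ DMSO, from 6241192 to 7712481 in CD138+ GSK-J4 and from 2636004 to 13190021 in naive cells. At 1 RPKM a gene of median length rested on 8.91 reads in the shallowest library (naive replicate 2) and on 44.6 in the deepest. Levels below are RPKM, mean ± SD over n = 3 libraries, and log2 changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Adjusted p-values are from limma. The first principal component, with 74.2% of the variance, parted naive from cultured cells, and the second, with 17.8%, parted GL7+ from CD138+ cells.

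The first comparison asked which transcripts differed in CD138+ cells after culture with GSK-J4. Among mature B cell genes several fell. Fcer2a, which encodes the low-affinity IgE receptor CD23, went from 8.82 ± 1.36 RPKM with DMSO to 1.76 ± 0.170 with GSK-J4 (log2 change -1.83, adjusted p = 9.2e-08). Cd22, an inhibitory co-receptor of the B cell receptor, went from 34.7 ± 2.68 to 11.5 ± 3.18 (-1.54, 9.5e-06), and Pax5, the transcription factor that maintains B cell identity, from 41.1 ± 3.31 to 20.3 ± 3.98 (-0.99, 4.1e-05). The metallothionein genes Mt1 and Mt2, whose products bind zinc and other metals, rose from 7.93 ± 0.766 to 131 ± 10.8 (3.89, 7.3e-12) and from 3.92 ± 1.17 to 102 ± 7.58 (4.41, 1.2e-09).

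**Figure D1:**
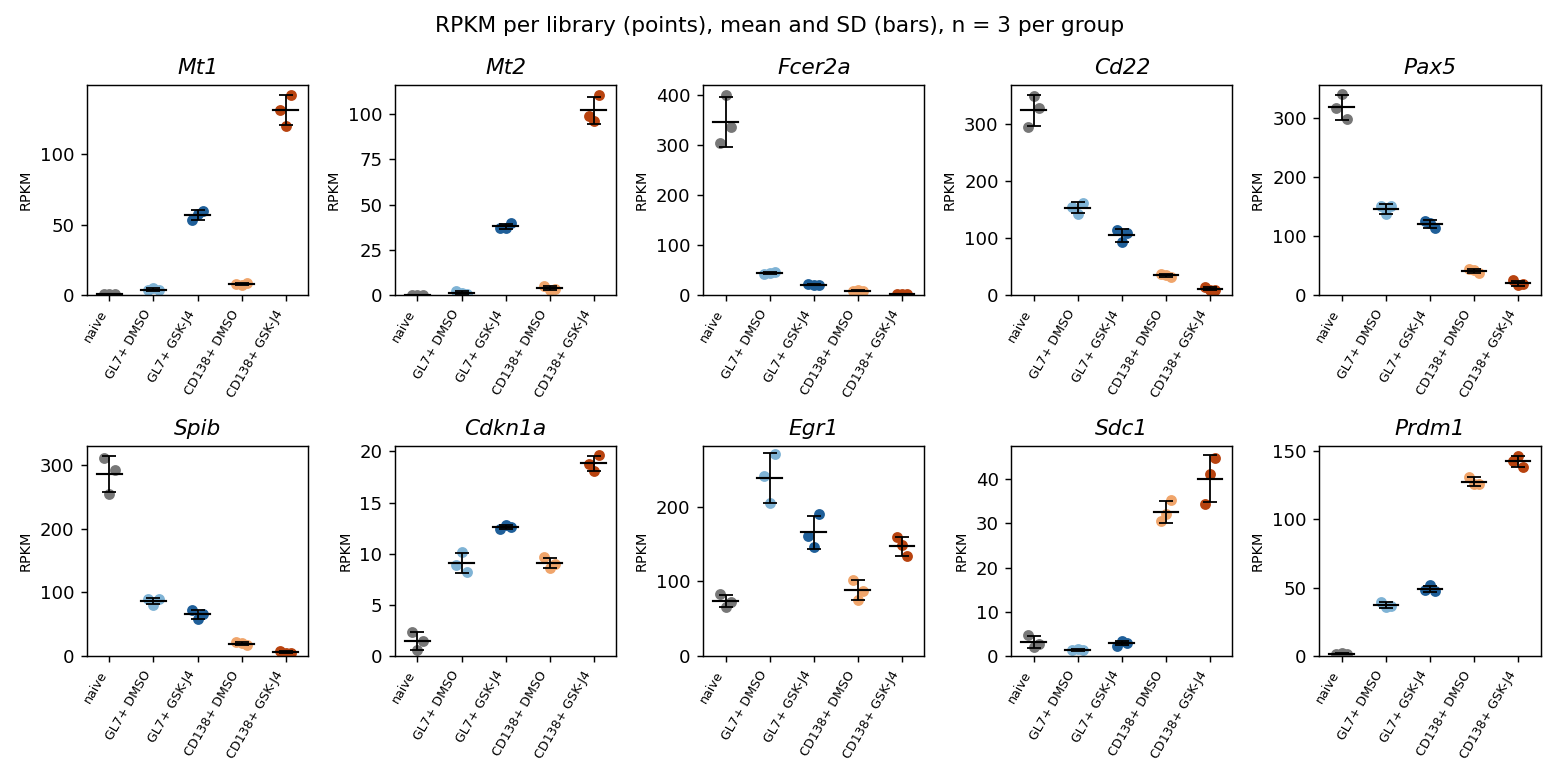
RPKM of 10 genes in each of the 15 libraries (points) of the 5 groups on linear axes that start at 0, with the group mean and SD (bars, n = 3). Mt1 and Mt2 stood higher in all GSK-J4 libraries than in all DMSO libraries, and Fcer2a, Cd22, Pax5 and Spib stood lower in CD138+ GSK-J4 than in CD138+ DMSO libraries.

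The mature B cell list had 20 of its 26 tested members lower and 1 higher (20 and 1 adjusted over the list alone), with a median log2 change of -0.48 (camera adjusted p = 7.2e-14, and adjusted p = 0.066 with an estimated correlation). Spib, an Ets factor of B cells, fell by 1.57 on the log2 scale from 19.2 ± 2.43 to 5.91 ± 1.66, and Id3, an inhibitor of E proteins, fell by 1.45 from 7.86 ± 0.803 to 2.25 ± 0.400. Of 15 tested genes of activated B cells 8 fell and none rose (9 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 4.6e-05, and adjusted p = 0.089 with an estimated correlation). They included Cd83, a maturation marker, at -1.15, Cd86, a co-stimulatory ligand, at -1.07, Batf at -0.58 and Irf8 at -0.53. Ltb, which encodes lymphotoxin beta, fell from 11.8 ± 1.51 to 3.58 ± 0.767 (log2 change -1.49, adjusted p = 1.2e-05).

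Among the largest rises beside the metallothioneins, Lgals3bp, a secreted galectin ligand, rose from 16.8 ± 1.23 to 45.4 ± 2.90 (log2 change 1.38, adjusted p = 9.2e-08), and Mnda, an interferon-inducible gene whose reads can be shared with close paralogs, from 4.46 ± 0.306 to 12.9 ± 0.226 (1.35, 1.3e-06). On the log2 scale Serpine2, a protease inhibitor, rose by 1.24, Cdkn1a, the cell cycle inhibitor p21, by 0.98 from 9.09 ± 0.524 to 18.8 ± 0.751, Usp18, a brake on interferon signalling, by 0.86, and Vkorc1, of the vitamin K cycle, by 0.75. The short RNA genes Snord73a (listed at 0 in the GSK-J4 libraries, 0 to 6 reads per library) and Mir3064 (2 to 34 reads) also passed the test as lower. Neither passed with the mouse as a block (adjusted p = 0.077 and 0.2), and no fold is given for them. Snord73a also missed the threshold without any 1 of the 6 CD138+ libraries other than DMSO replicate 2 (0.052 to 0.066), and Mir3064 without CD138+ DMSO replicate 1 or 3 or GSK-J4 replicate 1 or 4 (0.12, 0.19, 0.078 and 0.2), with TMM scaling (0.054), quantile normalization (0.063) and a pseudocount of 0.1 (0.052).

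DNA replication genes rose with GSK-J4 in CD138+ cells. Of 21 genes of S phase 7 rose and none fell (8 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 1.8e-07). This was the only list of this comparison past the threshold with an estimated correlation (adjusted p = 0.023). Ccne2, the cyclin of S phase entry, went from 7.12 ± 0.983 to 12.4 ± 2.41 (log2 change 0.71), Pcna, the polymerase clamp, from 319 ± 11.9 to 393 ± 15 (0.30), and Rrm2, of nucleotide synthesis, from 211 ± 7.15 to 250 ± 2.57 (0.24). Of 20 genes of G2 and M phase 0 passed limma's test over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05 and voom called 3 (median 0.01, camera adjusted p = 0.53). Foxm1 was among those with the smallest p (adjusted p = 0.06, and 0.041 with TMM scaling).

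Plasma cell genes changed little. Of 19 plasma cell genes only Ell2, an elongation factor of immunoglobulin transcripts, passed the test (131 ± 4.55 to 172 ± 4.32, log2 change 0.38, adjusted p = 0.0018; 1 gene adjusted over the list alone). The list median was 0.12 (camera adjusted p = 0.0025, and adjusted p = 0.2 with an estimated correlation). The regulators of plasma cell identity had log2 changes of 0.16 for Prdm1 (adjusted p = 0.36), 0.10 for Irf4 (0.28), 0.16 for Xbp1 (0.32) and 0.29 for Sdc1 (0.34). Of 24 genes of the unfolded protein response 5 rose (6 adjusted over the list alone), among them the chaperone Calr from 1420 ± 43.8 to 1750 ± 24.4 RPKM (log2 change 0.30) and the vesicle coat gene Sec24d (0.25). The list median was 0.12 (camera adjusted p = 4.6e-05, and adjusted p = 0.27 with an estimated correlation).

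Of 14 targets of p53, a DNA damage response factor, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The list had a median of 0.19 (camera adjusted p = 5.4e-04, and adjusted p = 0.2 with an estimated correlation). Beside Cdkn1a they included Mdm2, the ubiquitin ligase of p53, at 0.48, Zmat3 at 0.44 and Ccng1 at 0.34. Of 18 interferon response genes 6 rose and 2 fell (7 and 2 adjusted over the list alone). The list median was 0.11 (camera adjusted p = 0.0086, and adjusted p = 0.45 with an estimated correlation), and 0.07 without CD138+ GSK-J4 replicate 1. Zbp1, a nucleic acid sensor, rose from 57.3 ± 2.23 to 82.4 ± 1.52, and Oas1a, whose reads can be shared with close paralogs, by 0.87. Of 17 immediate early genes, which respond to stimuli within minutes, 4 rose and 1 fell (6 and 2 adjusted over the list alone). The median of the list was 0.15 (camera adjusted p = 0.0042, and adjusted p = 0.45 with an estimated correlation), and 0.24 with the mouse as a block. Egr1, a factor induced by growth signals, rose from 88.1 ± 13.4 to 147 ± 12.6 and Ier2 from 40.6 ± 2.24 to 64.1 ± 0.690, while Klf2, a factor of lymphocyte quiescence, fell by 1.01. Of 16 genes of the NRF2 and metal response 4 rose and 1 fell (5 and 1 adjusted over the list alone). The list had a median of 0.05 and a mean of 0.52, the latter set by Mt1 and Mt2 (camera adjusted p = 0.0027, and adjusted p = 0.066 with an estimated correlation). The median was 0.03 with the mouse as a block or without CD138+ GSK-J4 replicate 2, and 0.08 with quantile normalization.

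Lower lists included those of NF-kB targets, hypoxia and glycolysis, ATF4 targets and oxidative phosphorylation. Of 20 NF-kB targets 9 fell and 2 rose (13 and 6 adjusted over the list alone), with Nfkb1 at -0.36 and Nfkb2 at -0.39. Across the list the median was -0.21 (camera adjusted p = 0.023, and adjusted p = 0.23 with an estimated correlation). Of 21 genes of hypoxia and glycolysis 8 fell and none rose (10 and 1 adjusted over the list alone). Over the whole list the median was -0.31 (camera adjusted p = 2.6e-04, and adjusted p = 0.46 with an estimated correlation). Pgk1, a glycolytic kinase, went from 669 ± 51.8 to 466 ± 29.7 RPKM, and Ldha, lactate dehydrogenase, from 632 ± 52.1 to 471 ± 18.3. Of 19 targets of ATF4, the amino acid stress factor, 5 fell (5 adjusted over the list alone), with Trib3 at -1.20, Atf3 at -0.96 and Cth at -0.74 (adjusted p = 0.23 for Cth with a pseudocount of 0.1). As a whole the list had a median of -0.11 (camera adjusted p = 0.011, and adjusted p = 0.45 with an estimated correlation). Of 20 genes of oxidative phosphorylation 5 fell (8 adjusted over the list alone), with Atp5a1, a subunit of ATP synthase, at -0.25. For the list the median was -0.12 (camera adjusted p = 0.011, and adjusted p = 0.46 with an estimated correlation).

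The targets of the drug did not pass the test at the RNA level in CD138+ cells. Kdm6a stood at 27.7 ± 1.47 RPKM with DMSO and 29.8 ± 2.45 with GSK-J4 (adjusted p = 0.46), Kdm6b at 4.12 ± 0.321 and 3.69 ± 0.137 (0.51), and Ezh2, the methyltransferase that deposits H3K27me3, at 92.1 ± 1.83 and 93.7 ± 3.11 (0.77). Of 18 genes of Polycomb complexes and H3K27 demethylases none rose and 2 fell (3 adjusted over the list alone); both, Cbx7 and Rbbp4, missed the threshold with the mouse as a block (adjusted p = 0.16 and 0.085), Cbx7 with quantile normalization (0.069) and Rbbp4 with TMM scaling (0.051). The list had a median of -0.11 (camera adjusted p = 0.14). Without single libraries Cbx7 also missed it (CD138+ DMSO replicate 1 or 3 or GSK-J4 replicate 4, adjusted p = 0.11, 0.13 and 0.13), as did Rbbp4 (CD138+ GSK-J4 replicate 1 or DMSO replicate 2, 0.058 and 0.061). Of 17 other JmjC demethylases 3 fell, Kdm4a (-0.25), Kdm4b (-0.34) and Kdm5b (-0.38) (3 adjusted over the list alone). The list median was -0.10 (camera adjusted p = 0.14). Kdm4b missed the threshold without CD138+ DMSO replicate 2 or GSK-J4 replicate 4 (adjusted p = 0.053 and 0.052), and Kdm5b without DMSO replicate 1 or 2 or GSK-J4 replicate 1 or 4 (0.094, 0.11, 0.096 and 0.098) and with quantile normalization (0.099). Of 6 inhibitors of cyclin-dependent kinases Cdkn1a rose and Cdkn2a, the locus of p16 and p19ARF and a textbook Polycomb target, fell from 18.4 ± 0.874 to 12.4 ± 2.69 (log2 change -0.55, adjusted p = 0.0037; 1 and 1 adjusted over the list alone). Only 1 of 24 developmental Polycomb targets, Hoxb4 (named after its value was seen), passed the filter on low values, and its log2 change was -0.03. Bach2 had a log2 change of -0.12 (adjusted p = 0.48) and Bcl6 of 0.10 (0.61).

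The other lists missed the camera threshold in CD138+ cells. Of 18 genes of MYC and ribosome biogenesis 2 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.81), with Myc itself at 0.40 (adjusted p = 0.0092). Of 20 cholesterol synthesis genes 2 fell, Lss and Mvd (2 adjusted over the list alone, camera adjusted p = 0.21), with Mvd past the threshold neither without CD138+ DMSO replicate 2 nor without GSK-J4 replicate 2 (adjusted p = 0.058 and 0.052). Of 11 apoptosis regulators 1 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.81), with Bcl2, a survival factor, at -0.70. Of markers of other cell types, 5 T cell genes were tested and 1 fell, Cd28 (1 adjusted over the list alone). Cd28 stood at 7.56 RPKM in CD138+ DMSO cells, where the median over 10 T cell markers was 0.067. Its fall alone is therefore no measure of T cells. Of 6 dendritic cell genes 1 fell, Flt3 (1 adjusted over the list alone), and of 2 NK cell genes 1 fell, Il2rb, named after its value was seen (1 adjusted over the list alone). Of 9 myeloid and 4 erythroid or platelet genes limma called 0 and 0 over all genes or adjusted over the list alone, 1 and 0 had an unadjusted p under 0.05, and voom called 1 and 0. Median, mean and test differed in sign for the lists of kinase inhibitors, MYC and ribosome biogenesis, T cell and myeloid markers, none of which passed.

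In all, 1437 of 10866 tested genes passed the limma test in CD138+ cells, 501 higher and 936 lower (adjusted p under 0.05, 13.2% of genes), and 38 of them changed at least 2-fold, 7 higher and 31 lower. With quantile normalization the split was 613 higher and 700 lower, 46.7% against 34.9% higher. The count was 927 with the mouse as a block, a fit that in effect leaves out CD138+ GSK-J4 replicate 4. It was 585 with all libraries thinned to the same depth and 2688 with library weights. It was 2182 without naive replicate 2, a library outside this comparison that enters the shared spread. It was 825 without CD138+ DMSO replicate 1 or without replicate 2, 864 without CD138+ DMSO replicate 3 and 957 without CD138+ GSK-J4 replicate 2.

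The second comparison asked the same of the GL7+ fraction. Mt1 rose from 4.03 ± 0.774 RPKM with DMSO to 56.8 ± 3.33 with GSK-J4 (log2 change 3.53, adjusted p = 2.8e-11) and Mt2 from 1.40 ± 0.685 to 38.0 ± 1.36 (4.06, 3.8e-09). Plasma cell genes rose: Prdm1, which encodes BLIMP-1, the repressor that drives plasma cell differentiation, went from 37.2 ± 2.07 to 49.2 ± 2.12 (0.40, 0.021), Irf4 from 127 ± 2.23 to 167 ± 6.90 (0.39, 7.2e-04), Xbp1, the factor of the secretory programme, from 200 ± 8.90 to 253 ± 16.9 (0.34, 0.029), and Sdc1 from 1.37 ± 0.152 to 2.88 ± 0.496 (0.71, 0.019). Among mature B cell genes, Fcer2a went from 44.4 ± 1.58 to 20.9 ± 1.02 (-1.05, 7.2e-05). The calls of Prdm1, Xbp1 and Sdc1 were lost without some single libraries, while their log2 changes stayed at 0.36 to 0.38, 0.31 to 0.33 and 0.63 to 0.69. Prdm1 missed the threshold without GL7+ DMSO replicate 2 or 3 or GSK-J4 replicate 2 (adjusted p = 0.067, 0.072 and 0.082) and with a pseudocount of 0.1 (0.087), Xbp1 without DMSO replicate 1 or 3 or GSK-J4 replicate 2 or 3 (0.088, 0.1, 0.11 and 0.096), and Sdc1 without the same libraries (0.064, 0.066, 0.081 and 0.065).

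Of 19 plasma cell genes 11 rose and none fell (13 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 1.3e-07, and adjusted p = 0.034 with an estimated correlation). Jchain, the joining chain of secreted antibodies, went from 267 ± 20.9 to 353 ± 23.5, and Ell2 from 41.9 ± 0.621 to 58.8 ± 4.01. Of 24 genes of the unfolded protein response 14 rose (16 adjusted over the list alone), led by Creld2 at 0.57, the chaperone Hsp90b1 at 0.49 and Sec24d at 0.46. The median of the list was 0.27 (camera adjusted p = 1.1e-10, and adjusted p = 0.08 with an estimated correlation). Of 21 S phase genes 13 rose (18 adjusted over the list alone), with Rrm2 at 0.49, Cdc6 at 0.48 and Mcm4 at 0.33. Across the list the median was 0.26 (camera adjusted p = 1.7e-14, and adjusted p = 0.0015 with an estimated correlation). Of 20 G2 and M phase genes limma called 0 over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05 and voom called 3 (camera adjusted p = 0.23). Of 18 genes of MYC and ribosome biogenesis 7 rose (14 adjusted over the list alone), with Srm at 0.38 and Nolc1 at 0.35. Over the whole list the median was 0.23 (camera adjusted p = 4.1e-08, and adjusted p = 0.08 with an estimated correlation). Of 16 NRF2 and metal response genes 5 rose (7 adjusted over the list alone). As a whole the list had a median of 0.15 and a mean of 0.56, the latter set by Mt1 and Mt2 (camera adjusted p = 6.5e-05, and adjusted p = 0.015 with an estimated correlation). Of 18 interferon response genes 3 rose, Zbp1, Usp18 and Oas1a (5 adjusted over the list alone); without GL7+ DMSO replicate 2 the list missed the threshold (adjusted p = 0.062). For the list the median was 0.13 (camera adjusted p = 0.0074, and adjusted p = 0.35 with an estimated correlation). It was 0.08 without GL7+ DMSO replicate 2 or GSK-J4 replicate 1 or 3, and 0.20 without GSK-J4 replicate 2.

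Of 26 mature B cell genes 16 fell and 1 rose (20 and 1 adjusted over the list alone). The list had a median of -0.32 (camera adjusted p = 2.2e-09, and adjusted p = 0.086 with an estimated correlation). Fcrl1 fell from 73.1 ± 4.97 to 54.9 ± 2.92, while Cr2, the complement receptor CD21, rose from 8.23 ± 0.303 to 12.1 ± 0.189. Pax5 stood at 146 ± 8.02 and 120 ± 6.43 (log2 change -0.28, adjusted p = 0.091). Of 21 genes of hypoxia and glycolysis 9 fell (12 adjusted over the list alone), with Pdk1 at -0.65 and Pgk1 at -0.41 (adjusted p = 0.053 for Pgk1 without GL7+ GSK-J4 replicate 3). The list median was -0.29 (camera adjusted p = 1.9e-05, and adjusted p = 0.35 with an estimated correlation). Of 17 immediate early genes 8 fell (10 adjusted over the list alone), with Klf2 at -0.85, Junb at -0.53 and Zfp36 at -0.46. The median of the list was -0.34 (camera adjusted p = 9e-06, and adjusted p = 0.19 with an estimated correlation). Of 20 cholesterol synthesis genes 8 fell (10 adjusted over the list alone), with Mvd at -0.44. Across the list the median was -0.22 (camera adjusted p = 6.7e-06, and adjusted p = 0.061 with an estimated correlation). Of 19 ATF4 targets 6 fell (6 adjusted over the list alone), with Cth at -0.84 and Trib3 at -0.78 (adjusted p = 0.18 for Cth with a pseudocount of 0.1). Over the whole list the median was -0.12 (camera adjusted p = 0.0016, and adjusted p = 0.27 with an estimated correlation), and -0.19 with quantile normalization.

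Other JmjC demethylases fell in GL7+ cells, 5 of 17 with none higher (6 adjusted over the list alone). As a whole the list had a median of -0.08 (camera adjusted p = 0.0037, and adjusted p = 0.27 with an estimated correlation), and of -0.14 without GL7+ DMSO replicate 2. They included Kdm5b at -0.64, Kdm4b at -0.45 and Kdm4a at -0.36. Among 18 Polycomb and H3K27 demethylase genes 3 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.95). Ezh2 rose from 111 ± 2.68 to 136 ± 2.73 (log2 change 0.29, adjusted p = 5.5e-04), while Cbx7 (-0.40) and Cbx8 (-0.51), readers of the mark, fell. Cbx7 missed the threshold without GL7+ DMSO replicate 3 (adjusted p = 0.054) and Cbx8 without DMSO replicate 2 or GSK-J4 replicate 2 (0.06 and 0.072). Kdm6a stood at 22.5 ± 1.51 and 22.6 ± 1.99 (adjusted p = 0.99) and Kdm6b at 7.54 ± 1.68 and 5.95 ± 0.342 (adjusted p = 0.11), with Kdm6b past the threshold without GL7+ DMSO replicate 2 (adjusted p = 0.0058). Of 6 kinase inhibitors 3 fell (3 adjusted over the list alone), Cdkn2a from 23.1 ± 1.07 to 10.2 ± 0.562 (log2 change -1.10, adjusted p = 7.2e-05), Cdkn1b at -0.42 and Cdkn2d at -0.54. Cdkn1b missed the threshold without GL7+ DMSO replicate 1 or GSK-J4 replicate 2 or 3 (adjusted p = 0.062, 0.065 and 0.076), and Cdkn2d without DMSO replicate 1 or GSK-J4 replicate 2 (0.055 and 0.06). The list had a camera adjusted p = 0.051, and 0.025 with the mouse as a block. Hoxb4, the 1 developmental Polycomb target tested, had a log2 change of -0.10.

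Further single genes among the largest rises in GL7+ cells were Mnda (2.95 ± 0.315 to 6.71 ± 0.441, log2 change 0.97), Tubb6, a tubulin (0.94), Rgcc (0.87), Pik3cg, a phosphoinositide kinase (0.87), and Ccl22, a chemokine (0.85). Rgcc missed the threshold without GL7+ DMSO replicate 3 (adjusted p = 0.052). Slpi, a protease inhibitor, went from 12 ± 2.31 to 31.9 ± 4.48 (adjusted p = 0.044) and missed the threshold with the mouse as a block (0.07), with a pseudocount of 0.1 (0.38) and without any 1 of the 6 GL7+ libraries (0.067 to 0.15). Among the largest falls were Gstt1, a glutathione transferase (10.9 ± 1.66 to 2.97 ± 0.422, log2 change -1.58), Aldoc, a glycolytic aldolase (-1.42), Ltb (39.4 ± 3.44 to 14.5 ± 3.09, -1.39), Mgarp (-0.95), Slc16a3, a lactate exporter (-0.92), and the short RNA gene Snord35b, which rests on 3 to 16 reads. Slc16a3 missed the threshold without GL7+ DMSO replicate 1 or 2 or GSK-J4 replicate 3 (adjusted p = 0.059, 0.055 and 0.065) and with a pseudocount of 0.1 (0.17), and Snord35b without DMSO replicate 1 or 3 or GSK-J4 replicate 1 or 3 (0.13, 0.13, 0.079 and 0.15), with a pseudocount of 0.1 (0.28) and with quantile normalization (0.055). Of 20 NF-kB targets 4 rose and 5 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.12). The chemokine genes Ccl3 (1.26 ± 0.103 to 4.30 ± 1.37) and Ccl4 (1.18 ± 0.689 to 4.54 ± 1.16) rose and Nfkb2 fell by 0.39. Of 15 activated B cell genes 2 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.45). Of 14 p53 targets 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.27). Of 20 oxidative phosphorylation genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.17). Of 11 apoptosis regulators 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.38). Among cell type markers, Flt3 of 6 dendritic cell genes fell (1 adjusted over the list alone), and Il2rb of 2 NK cell genes, named after its value was seen, rose (1 adjusted over the list alone), though not without GL7+ DMSO replicate 1 or 2 or GSK-J4 replicate 1 or 3 (adjusted p = 0.1, 0.11, 0.065 and 0.14). Of 5 T cell, 9 myeloid and 4 erythroid or platelet genes limma called 0, 0 and 0 over all genes or adjusted over the list alone, each list had 1 with an unadjusted p under 0.05, and voom called 0, 0 and 1. Median, mean and test differed in sign for the lists of Polycomb genes, NF-kB targets, T cell and myeloid markers.

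In GL7+ cells 1469 of 10866 genes passed the limma test, 631 higher and 838 lower (13.5%), and 14 of them changed at least 2-fold, 6 higher and 8 lower. With TMM scaling the split was 710 higher and 676 lower, 51.2% against 43% higher, so the balance of directions rests on the scaling. The count was 541 with all libraries thinned to one depth, 2256 in a fit of these 6 libraries alone, 2387 with voom on the recovered reads, 2968 with library weights and 2281 without naive replicate 2. It was 743 without GL7+ GSK-J4 replicate 2, 826 without GL7+ GSK-J4 replicate 3, 788 without GL7+ DMSO replicate 1 and 839 without GL7+ DMSO replicate 3.

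**Figure D2:**
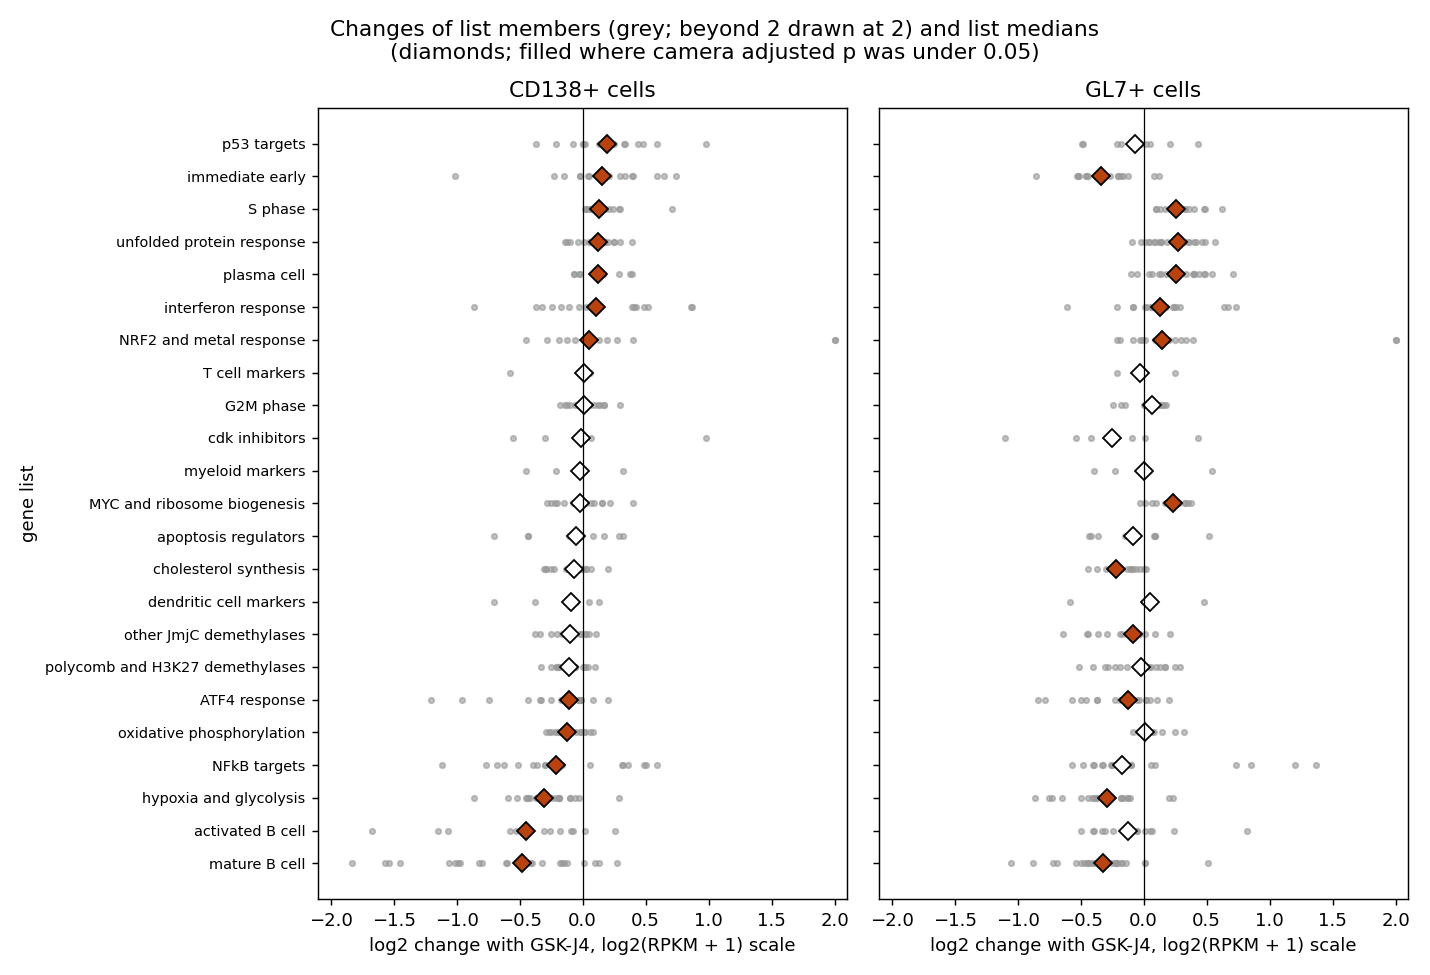
Log2 changes with GSK-J4 on the log2(RPKM + 1) scale of the members (grey points) of the 23 gene lists with at least 5 tested members, and each list's median (diamonds, filled where camera's adjusted p was under 0.05), in CD138+ cells (left, 13 lists filled) and GL7+ cells (right, 12 lists filled). Mt1 and Mt2 lie beyond the axis and are drawn at its end, 2. The mature B cell list lay at -0.48 and -0.32, and the immediate early list at 0.15 and -0.34.

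The third comparison tested whether the change with GSK-J4 differed between the CD138+ and GL7+ fractions. Several immediate early genes had higher changes in CD138+ than in GL7+ cells. Egr1 had a log2 change of 0.74 in CD138+ and -0.52 in GL7+ cells, a difference of 1.26 (adjusted p = 0.0093), Ier2 of 0.65 and -0.20 (difference 0.84, adjusted p = 0.0013), and Zfp36, a destabiliser of cytokine transcripts, of 0.34 and -0.46 (difference 0.81, adjusted p = 0.011). Several B cell regulators had lower changes in CD138+ than in GL7+ cells: Spib of -1.57 and -0.39 (difference -1.18, adjusted p = 0.017), Zbtb32, a zinc finger repressor, of -1.28 and -0.23 (-1.05, 0.0043), and Pax5 of -0.99 and -0.28 (-0.72, 0.033). Il2rb, the beta chain of the IL-2 receptor, had changes of -0.73 and 0.43, a difference of -1.16 (adjusted p = 0.011).

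The other named differences were positive for Junb (0.74) and Vkorc1 (0.77) and negative for Gypc (-1.01) and the mitochondrial tRNA synthetase gene Lars2 (-1.22). Members of the mature B cell list with a lower change in CD138+ cells were Cd22 (difference -1.0), Id3 (-1.0) and Fcer2a (-0.77). Among all these genes, the differences of Pax5, Cd22, Id3, Fcer2a, Gypc, Vkorc1 and Lars2 missed the threshold with the mouse as a block (adjusted p = 0.067, 0.08, 0.063, 0.066, 0.057, 0.13 and 0.11), as did Pax5 and Vkorc1 with quantile normalization (0.054 and 0.089) and Vkorc1 with a pseudocount of 0.1 (0.06). In fits that each left out 1 of the 12 cultured libraries, Egr1, Ier2, Zfp36, Junb, Zbtb32, Il2rb and Gypc passed in all 12. Spib passed in 9 of them, missing the threshold without CD138+ DMSO replicate 1, CD138+ GSK-J4 replicate 2 or GL7+ GSK-J4 replicate 3 (adjusted p = 0.053, 0.052 and 0.063). Of the others, Id3 passed in 7, Fcer2a in 6, Lars2 in 4, Cd22 in 3, Pax5 in 2 and Vkorc1 in 0, with adjusted p up to 0.066, 0.076, 0.091, 0.082, 0.098 and 0.12. The differences for Kdm6a (0.10), Kdm6b (0.15), Prdm1 (-0.24), Irf4 (-0.29), Xbp1 (-0.18), Sdc1 (-0.42), Bach2 (-0.13) and Bcl6 (0.24) did not pass the test (adjusted p = 0.8, 0.75, 0.51, 0.1, 0.61, 0.51, 0.79 and 0.55). That of Ezh2 did (-0.27, adjusted p = 0.04), but not with the mouse as a block (0.12) or quantile normalization (0.076), and in 1 of the 12 fits without a library (adjusted p up to 0.12).

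By list, 11 of 23 passed camera for the difference, and none of them with an estimated correlation. The immediate early list had a median difference of 0.32, with 4 of 17 genes past the test (9 adjusted over the list alone, camera adjusted p = 1.1e-11, and adjusted p = 0.083 with an estimated correlation). The p53 targets had a median of 0.27, with 2 of 14 genes past the test (5 adjusted over the list alone, camera adjusted p = 9.3e-08, and adjusted p = 0.083 with an estimated correlation). The list of activated B cell genes had a median of -0.46, with 3 of 15 genes past the test (8 adjusted over the list alone, camera adjusted p = 2.9e-05, and adjusted p = 0.083 with an estimated correlation). The mature B cell list had a median of -0.21, with 6 of 26 genes past the test (9 adjusted over the list alone, camera adjusted p = 1e-04, and adjusted p = 0.26 with an estimated correlation), and of -0.13 with quantile normalization. Median, mean and test differed in sign for ATF4 targets, interferon response genes, apoptosis regulators, T cell and myeloid markers, none of which passed.

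Of 10866 genes 105 passed the test of the difference, 35 with a higher and 70 with a lower change in CD138+ cells, and 9 of them differed at least 2-fold. The count was 32 with the mouse as a block, which again in effect leaves out CD138+ GSK-J4 replicate 4. It was 7 with all libraries thinned to the same depth, 832 with library weights, 361 without naive replicate 2 and 53 with no filter on low values. The count was also 462 in a fit of the 12 cultured libraries alone and 318 with voom on the recovered reads. It lay between 18 and 66 without each 1 of the cultured libraries except CD138+ GSK-J4 replicate 1, without which it was 118, and was lowest without GL7+ GSK-J4 replicate 3.

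**Figure D3:**
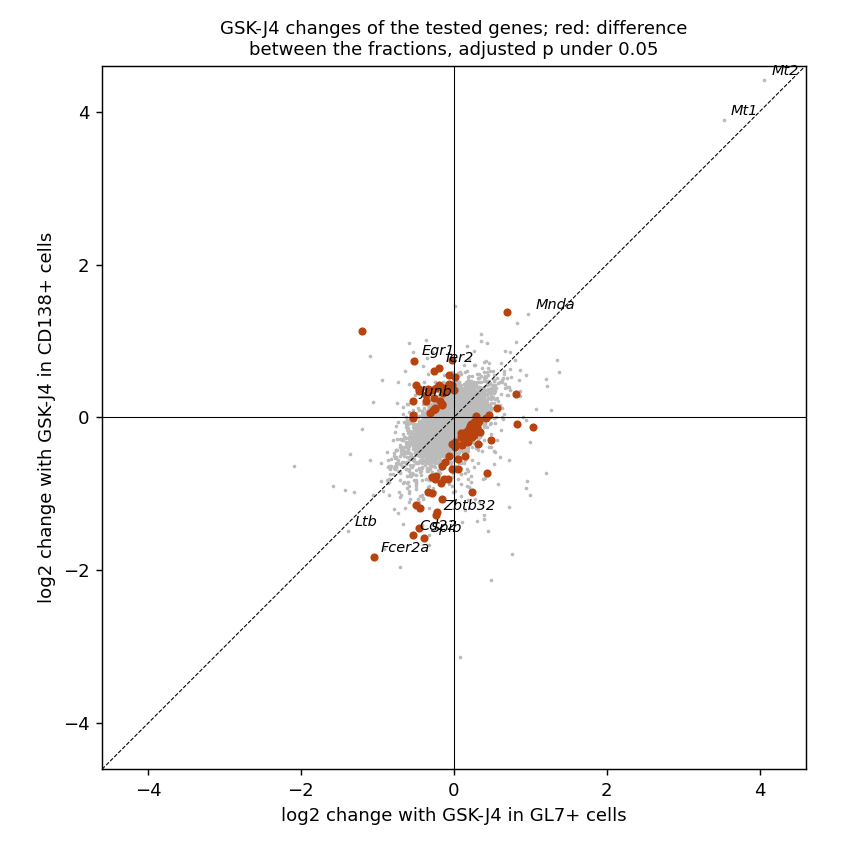
Log2 change with GSK-J4 of 10866 genes in GL7+ cells (horizontal) and in CD138+ cells (vertical), both on the log2(RPKM + 1) scale, with the 105 genes whose change differed between the fractions in red and the line of equal change dashed. Mt1 and Mt2 lay far from the other genes in both fractions, and Egr1, Ier2 and Junb lay above the dashed line.

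The changes with GSK-J4 in both fractions were correlated across genes, which are not independent replicates (Pearson r = 0.51, Spearman 0.48, 10866 genes). These comparisons share no library, but they share mice. Simulated unchanged groups gave a mean r of 0.00, which was set in advance because each library was drawn independently. It does not cover links through the mice or the cultures. Of 501 genes that rose in CD138+ cells 187 also rose in GL7+ cells, where independent lists would share 29.1, and of 936 that fell 377 also fell, where independent lists would share 72.2. Among them were Mt1, Mt2, Mnda, Usp18 and Zbp1 on the higher side and Fcer2a, Ltb, Cd83, Cdkn2a, Cth and Trib3 on the lower side. Opposite calls were fewer than independent lists would share: 13 genes rose in CD138+ and fell in GL7+ cells (38.6 for independent lists), and 9 did the reverse (54.4).

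The fourth comparison set CD138+ against GL7+ cells cultured with DMSO. Plasma cell genes stood far higher in CD138+ cells: Sdc1, the antigen used for enrichment, at 32.6 ± 2.44 against 1.37 ± 0.152 RPKM (log2 difference 3.83, adjusted p = 3.9e-10), and Prdm1 at 128 ± 2.93 against 37.2 ± 2.07 (1.75). Xbp1 stood at 839 ± 49.3 against 200 ± 8.90 (2.06), Irf4 at 350 ± 19.0 against 127 ± 2.23 (1.45) and Jchain at 1590 ± 55.8 against 267 ± 20.9 (2.57). Of mature B cell genes, Pax5 stood lower at 41.1 ± 3.31 against 146 ± 8.02 (-1.81) and Fcer2a at 8.82 ± 1.36 against 44.4 ± 1.58 (-2.22). Bach2 (-1.10) and Bcl6 (-1.01), regulators of germinal centre B cells, were lower as well. The demethylase genes moved apart, with Kdm6b lower in CD138+ cells (4.12 ± 0.321 against 7.54 ± 1.68, adjusted p = 6e-05) and Kdm6a higher (27.7 ± 1.47 against 22.5 ± 1.51, adjusted p = 0.0077), while Ezh2 was lower (-0.26, 5.3e-05).

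Of 19 plasma cell genes 18 were higher (18 adjusted over the list alone). For the list the median was 2.06 (camera adjusted p = 3.1e-17, and adjusted p = 0.0043 with an estimated correlation). Of 24 genes of the unfolded protein response 23 were higher (23 adjusted over the list alone). The list had a median of 1.18 (camera adjusted p = 4.9e-19, and adjusted p = 0.038 with an estimated correlation). Of 26 mature B cell genes 23 were lower (23 adjusted over the list alone). The list median was -1.24 (camera adjusted p = 8e-10, and adjusted p = 0.14 with an estimated correlation). Of 20 NF-kB targets 16 were lower and 2 higher (16 and 2 adjusted over the list alone). The median of the list was -0.82 (camera adjusted p = 5.4e-04, and adjusted p = 0.075 with an estimated correlation). Of 18 MYC and ribosome biogenesis genes 13 were lower and 3 higher (13 and 4 adjusted over the list alone). Across the list the median was -0.48 (camera adjusted p = 0.016, and adjusted p = 0.57 with an estimated correlation). Of 20 cholesterol synthesis genes 15 were lower and 1 higher (16 and 1 adjusted over the list alone). Over the whole list the median was -0.36 (camera adjusted p = 0.02, and adjusted p = 0.37 with an estimated correlation). Median, mean and test differed in sign for other JmjC demethylases, ATF4 targets, apoptosis regulators, myeloid and dendritic cell markers, none of which passed. The largest single rises were Ly6c2, whose reads can be shared with its close paralog Ly6c1 (4.55), Sdc1, Tnfrsf17, the receptor BCMA of plasma cells (0.405 ± 0.145 to 12.5 ± 1.80, 3.26), Cacna1h (3.02) and Evi5 (3.02). Among the largest falls were the short RNA gene Snord35b, Gbp2 (-2.29), Fcer2a and Tnf (-2.20).

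Of 10866 genes 6379 passed the limma test between the fractions, 2374 higher and 4005 lower in CD138+ cells, and 769 differed at least 2-fold. Scaling each library by TMM factors gave 2979 higher and 2934 lower, 50.4% against 37.2% higher, so that the balance of directions rests on the scaling.

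The change with GSK-J4 in CD138+ cells went with this difference across genes. Of 936 genes that fell with GSK-J4 in CD138+ cells 703 were also lower in CD138+ than GL7+ cells under DMSO, where independent lists would share 345, and of 501 that rose 255 were also higher, where independent lists would share 109. The correlation was 0.35 (covariance 0.0446), against a simulated -0.50 (covariance -0.00649) from the CD138+ DMSO libraries that both comparisons share with opposite signs. In GL7+ cells the correlation with the same difference was 0.37 (covariance 0.0434). Unchanged groups that share the GL7+ DMSO libraries gave a simulated 0.50 (covariance 0.00651). The r thus did not stand apart from the sharing, while the covariance exceeded the simulated one by 0.0369.

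The fifth comparison set cultured DMSO cells against naive B cells. Proliferation genes rose in both fractions: Top2a, a mitotic topoisomerase, went from 6.61 ± 0.535 RPKM in naive to 168 ± 5.65 in GL7+ and 179 ± 3.10 in CD138+ cells, and Rrm2 from 4.76 ± 0.398 to 170 ± 2.18 and 211 ± 7.15. Ezh2 rose from 13.0 ± 0.270 to 111 ± 2.68 and 92.1 ± 1.83, while Kdm6b fell from 30.6 ± 1.31 to 7.54 ± 1.68 and 4.12 ± 0.321. Bcl6 fell from 50.4 ± 7.85 to 3.86 ± 0.117 and 1.41 ± 0.230. Prdm1 rose from 1.75 ± 0.578 to 37.2 ± 2.07 and 128 ± 2.93.

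Against naive cells, the S phase and G2 and M phase lists were higher in GL7+ cells (medians 2.60 and 4.28, 20 of 21 genes higher with 1 lower and 20 of 20 higher, the same counts adjusted over the list alone, camera adjusted p = 9.8e-10 and 1.1e-10, and adjusted p = 0.0091 and 0.026 with an estimated correlation). The same lists were higher in CD138+ cells (medians 2.31 and 4.18, 21 of 21 and 20 of 20 genes, likewise adjusted over the list alone, camera adjusted p = 6.7e-10 and 6.6e-11, and adjusted p = 0.009 and 0.02 with an estimated correlation). All 20 cholesterol synthesis genes were higher in both fractions, also adjusted over the list alone (medians 2.46 and 2.08, camera adjusted p = 8.4e-10 and 2.3e-09, and adjusted p = 0.019 and 0.018 with an estimated correlation). The plasma cell list was higher in CD138+ cells, 19 of 19 genes, also adjusted over the list alone (median 3.58, camera adjusted p = 2.7e-09, and adjusted p = 0.018 with an estimated correlation). In GL7+ cells 13 of its genes were higher and 4 lower (14 and 4 adjusted over the list alone). As a whole the list had a median of 1.69 (camera adjusted p = 0.0029, and adjusted p = 0.16 with an estimated correlation). The mature B cell list was lower in GL7+ cells, 24 genes lower and 1 higher (24 and 1 adjusted over the list alone, median -1.72, camera adjusted p = 1.5e-08, and adjusted p = 0.14 with an estimated correlation). In CD138+ cells all 26 genes were lower, also adjusted over the list alone (median -3.01, camera adjusted p = 6.6e-11, and adjusted p = 0.069 with an estimated correlation). Immediate early genes were lower in cultured cells, 15 of 17 in each fraction, with 2 higher in GL7+ and 0 in CD138+ cells, the same counts adjusted over the list alone (medians -2.77 in GL7+ and -2.74 in CD138+ cells, camera adjusted p = 1.2e-05 in each, and adjusted p = 0.17 with an estimated correlation). Nr4a1, an early response gene of antigen receptor signalling, stood at 354 ± 23.8 RPKM in naive, 4.11 ± 0.582 in GL7+ and 1.67 ± 0.0976 in CD138+ cells. The labels give no culture time for naive cells, so cell state, culture and handling cannot be told apart for these genes.

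Genes of metabolism and secretion stood higher in cultured than in naive cells, with counts that were the same adjusted over the list alone. Of 24 genes of the unfolded protein response 22 were higher and 1 lower in GL7+ cells (median 1.47, camera adjusted p = 1e-07, and adjusted p = 0.14 with an estimated correlation) and 23 and 1 in CD138+ cells (2.72, 6.6e-11, and adjusted p = 0.069 with an estimated correlation). Of 20 oxidative phosphorylation genes 20 were higher in GL7+ cells (median 1.28, camera adjusted p = 1.5e-07, and adjusted p = 0.14 with an estimated correlation) and 19 in CD138+ cells (1.22, 8.5e-07, and adjusted p = 0.15 with an estimated correlation). Of 21 genes of hypoxia and glycolysis 19 were higher in GL7+ cells (median 2.45, camera adjusted p = 3.6e-07, and adjusted p = 0.24 with an estimated correlation) and 19 higher and 1 lower in CD138+ cells (2.25, 3e-06, and adjusted p = 0.28 with an estimated correlation). Of 19 ATF4 targets 16 were higher and 3 lower in each fraction (medians 2.54 in GL7+ and 2.73 in CD138+ cells, camera adjusted p = 6.8e-06 and 1.4e-05, and adjusted p = 0.14 and 0.13 with an estimated correlation). Of 18 MYC and ribosome biogenesis genes 17 were higher and 1 lower in GL7+ and 16 and 1 in CD138+ cells (medians 1.29 and 0.91, camera adjusted p = 6.8e-06 and 1.9e-04, and adjusted p = 0.14 and 0.18 with an estimated correlation).

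The p53 targets, 10 of 14 higher and 2 lower in GL7+ and 11 and 3 in CD138+ cells, also adjusted over the list alone (medians 0.89 and 0.66, camera adjusted p = 0.038 and 0.035, and adjusted p = 0.26 and 0.28 with an estimated correlation), passed in both. They missed the threshold with TMM scaling (0.053 and 0.067) and in GL7+ cells without naive replicate 2 (0.058). Other JmjC demethylases were lower, 11 of 17 with 3 higher in GL7+ and 13 with 3 higher in CD138+ cells, also adjusted over the list alone (medians -0.44 and -0.53, camera adjusted p = 0.043 and 0.021, and adjusted p = 0.32 and 0.28 with an estimated correlation). In GL7+ cells that list missed the threshold with the mouse as a block (0.054), with TMM scaling (0.055) and without GL7+ DMSO replicate 3 (0.051). In CD138+ cells its median was -0.32 with TMM scaling. The NRF2 and metal response list passed in CD138+ cells, with 11 of 16 genes higher and 5 lower, also adjusted over the list alone (median 1.26, camera adjusted p = 0.046, and adjusted p = 0.13 with an estimated correlation), but not with TMM scaling (0.078) or quantile normalization (0.053). In all, 14 of 23 lists passed camera in GL7+ and 15 in CD138+ cells, and 3 and 4 of them with an estimated correlation.

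The largest rises over naive cells were Zbtb32 (log2 change 6.32), Asns (6.08), Ube2c (5.17), Ccnb1 (5.12) and Slc16a3 (5.12) in GL7+ cells, and Asns (6.14), Hid1 (5.99), Tmed6 (5.71), Prdm1 (5.56) and Slc7a3 (5.52) in CD138+ cells. Markers of other blood cells stood higher in the naive group: Hba-a2, a globin gene with near-identical copies, at 137 ± 8.01 RPKM against 0.0257 ± 0.0445 in GL7+ cells, Hbb-bs at 156 ± 21.1 against 1.13 ± 0.672, and Lyz2, a myeloid gene, at 61.7 RPKM as the highest of its list (named after its value was seen). The myeloid list was lower in GL7+ cells, with 7 of 9 genes lower (7 adjusted over the list alone, camera adjusted p = 7.5e-04, and adjusted p = 0.21 with an estimated correlation). In CD138+ cells 9 of 9 were lower (9 adjusted over the list alone, camera adjusted p = 3.8e-04, and adjusted p = 0.18 with an estimated correlation). Other large falls were Icosl (-6.19 in GL7+ and -6.32 in CD138+ cells), Rasgef1b (-5.71 in GL7+ cells) and Plaur (-6.28 in CD138+ cells). The limma test called 8875 genes in GL7+ cells (4492 higher, 4383 lower, 3335 at least 2-fold) and 9066 in CD138+ cells (4340 higher, 4726 lower, 3870 at least 2-fold). TMM scaling moved the median log2 change of all genes in CD138+ against naive cells by 0.18, from -0.05 to 0.13, and the split to 5085 higher and 3922 lower (56.5% against 47.9% higher), so those changes and their balance rest on the scaling.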

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

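The tests of cell make-up in both fractions were chosen only after the result was seen. The change with GSK-J4 differed between CD138+ and GL7+ cells, by the test of the difference itself, for 24 named genes and 11 lists (0 lists with an estimated correlation), given here as CD138+ minus GL7+ log2 changes. Positive differences were 1.26 for Egr1, 0.84 for Ier2, 0.81 for Zfp36, 0.77 for Vkorc1, 0.74 for Junb, 0.65 for Bcl2l11, 0.51 for Zmat3 and 0.45 for Ccng1. Negative differences were -1.22 for Lars2, -1.18 for Spib, -1.16 for Il2rb, -1.05 for Zbtb32, -1.01 for Gypc, -1.0 for Cd22, -1.0 for Id3, -0.90 for Tnfrsf8, -0.77 for Fcer2a, -0.72 for Pax5, -0.65 for Cd83, -0.50 for Il5ra, -0.45 for Creld2, -0.33 for Rbbp4, -0.31 for Mybbp1a and -0.27 for Ezh2. With the mouse as a block 11 of the 24 stayed past the threshold. Of those not given in the comparison itself, Cd83, Il5ra, Rbbp4, Zmat3 and Bcl2l11 missed it with the block (adjusted p = 0.067, 0.083, 0.12, 0.087 and 0.063). Zmat3 also missed it with TMM scaling, quantile normalization and a pseudocount of 0.1 (0.056, 0.059 and 0.058), Rbbp4 and Mybbp1a with TMM scaling (0.083 and 0.062) and Tnfrsf8 with the pseudocount (0.37). In the 12 fits that each left out 1 cultured library Ccng1 passed in 8, Bcl2l11 in 6, Cd83 in 5, Creld2 in 4, Tnfrsf8 in 3, Il5ra in 2, Mybbp1a in 1, Zmat3 in 1 and Rbbp4 in 0, with adjusted p up to 0.066, 0.072, 0.074, 0.074, 0.083, 0.1, 0.14, 0.13 and 0.12.

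By list, the median differences were 0.32 for immediate early genes (camera adjusted p = 1.1e-11), 0.31 for kinase inhibitors (0.0032), 0.27 for p53 targets (9.3e-08), 0.12 for cholesterol synthesis (5.3e-04), -0.12 for S phase (4e-04), -0.17 for plasma cell genes (0.0092), -0.17 for the unfolded protein response (0.0014), -0.17 for oxidative phosphorylation (2.9e-05), -0.21 for mature B cell genes (1e-04), -0.22 for MYC and ribosome biogenesis (9.3e-08) and -0.46 for activated B cell genes (2.9e-05). None passed with an estimated correlation (adjusted p = 0.083, 0.12, 0.083, 0.12, 0.083, 0.24, 0.38, 0.24, 0.26, 0.098 and 0.083 in that order). The plasma cell list missed the threshold without GL7+ GSK-J4 replicate 2 (adjusted p = 0.068) or GL7+ DMSO replicate 3 (0.058).

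The mature B cell list was lower with GSK-J4 in CD138+ cells (20 of 26 genes lower, 1 higher) and GL7+ cells (16 and 1), though not with an estimated correlation (adjusted p = 0.066 and 0.086); fewer GL7+-like cells among CD138+ cells, or more CD138+-like cells among GL7+ cells, would move each gene by 1 share of its gap under DMSO. This was compared in genes at least 2-fold apart between the fractions under DMSO. Bootstrap intervals resampled genes, which are not independent, and leave out the spread between mice. In CD138+ cells the median was 19.9% for 19 mature B cell genes (95% bootstrap interval 17.7 to 24.3). It was 17.5% for 333 other genes lower in CD138+ cells (16.0 to 18.5), which overlaps, but 7.95% for 433 genes higher in CD138+ cells (6.06 to 10.5). In GL7+ cells the medians of these sets were 38.0% (25.2 to 43.3), 33.2% (30.1 to 35.9) and 6.36% (5.27 to 7.24), again less for the higher genes. As far as intervals over genes can tell, cell make-up alone is thus unlikely to account for the lower and higher genes together. The higher genes varied widely, with quartiles of -6.31% and 24.1% in CD138+ and 0.531% and 13.3% in GL7+ cells. The test cannot decide about the fall by itself. Other lower genes moved by a similar share, and a separate effect on the higher genes would leave the fall to make-up. Lower depth of the CD138+ GSK-J4 libraries had been taken to predict a median log2 change near 0 with all libraries thinned to the same depth, and it was -0.50. Thinning leaves the expected RPKM of each gene unchanged, so it could hardly have brought the median to 0. It therefore does not decide about depth. A drug effect on these genes within cells, a make-up change by itself or as part of it, and cells of intermediate state stay open. Of the genes higher in CD138+ cells, 16 plasma cell genes moved by a median of 6.25% of the gap in GL7+ cells (4.84 to 9.31). This was near the 6.36% of all higher genes, so a change of cell make-up stays open for the rise of plasma cell genes there.

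Of 17 immediate early genes 4 passed the test of the difference, all with a higher change in CD138+ cells (9 adjusted over the list alone), and the list passed camera but not with an estimated correlation (adjusted p = 0.083). Leaving out each of the 12 cultured libraries in turn gave a median difference of at least 0.32, which argues against a single library. Thinning to the same depth gave 0.43. Since thinning leaves the expected RPKM of each gene unchanged, this does not decide about unequal depth. These genes respond within minutes, and handling of the cells during enrichment may differ between samples, which was not tested. A difference in drug response between the fractions stays open as well.

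Other splits of the libraries were tried for each count. For the difference between fractions, 4 of 100 permutations of the drug labels within the fractions gave at least the real 105 genes, the real one included. Among the 18 that part as many mouse pairs as the real one 3 did (highest other 202). Permuting labels within a fraction also breaks up the change with GSK-J4 that both fractions share. These draws thus do not test the difference alone, so chance labelling cannot be excluded for it. The highest other count of all was 244, and the 3 draws above the real one (244, 202 and 123 genes) exchanged all 6 CD138+ labels while moving 2 GL7+ labels, or moved 4 GL7+ labels alone. They point to a structure of the samples, since exchanging the labels of 1 fraction turns the change that both share into a difference. The 3 against 3 comparisons have 10 splits, too few for a share under 0.05. As many genes or lists came from 1 of 10 splits for CD138+ cells (1437 genes, highest other 0; 13 lists, highest other 8) and 1 of 10 for GL7+ cells (1469 genes, highest other 0; 12 lists, highest other 10). For CD138+ against GL7+ cells it was 1 of 10 for genes (6379, highest other 1) and 4 of 10 for lists (6, highest other 6). Against naive cells it was 1 of 10 for GL7+ cells (8875, highest other 1) and 1 of 10 for CD138+ cells (9066, highest other 0). Among the 4 splits that part as many mouse pairs as the real one, the highest other counts were the same, except 5 lists for CD138+ against GL7+ cells and 0 genes for GL7+ against naive cells.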

How the results depend on the processing

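The fits with voom, with thinning, with the mouse as a random effect and without naive replicate 2 in comparisons of cultured cells were chosen only after the data were seen; the tests of the comparisons, their thresholds, the other alternatives and the gene lists were fixed before the data were examined. The cause of the shifts below was not tested except where named. The direction with more calls turned with TMM scaling for GL7+ GSK-J4 (710 higher, 676 lower), CD138+ against GL7+ cells (2979 and 2934) and CD138+ against naive cells (5085 and 3922). It also turned for GL7+ against naive cells with quantile normalization (4333 and 4528), no filter (4801 and 5473), voom (4473 and 4510) and only the contrast's libraries (4119 and 4183), and for CD138+ against naive cells with the stricter filter (3725 and 3642) and without naive replicate 1 (4318 and 4260) or 3 (4299 and 4261). For CD138+ against GL7+ cells it turned at 2-fold or more (429 and 340). For the difference between fractions it turned without CD138+ GSK-J4 replicate 2 (12 and 11) or GL7+ GSK-J4 replicate 3 (10 and 8), and the sides were equal at 0.01 (4 and 4). CD138+ GSK-J4 calls (1437) became 927 with the mouse as a block, whose construction sets the library without a mouse apart, 2688 with library weights, 585 thinned to one depth, 38 at 2-fold or more, 599 at 0.01, and 825 to 2182 without 1 library. GL7+ GSK-J4 calls (1469) became 2256 with only the contrast's libraries, 2968 with library weights, 2387 with voom, 541 thinned, 14 at 2-fold or more, 569 at 0.01, and 743 to 2281 without 1 library. Genes whose change differed between fractions (105) became 32 with the block, 462 with only the cultured libraries, 53 with no filter, 832 with library weights, 318 with voom, 7 thinned, 9 at 2-fold or more, 8 at 0.01, and 18 to 361 without 1 library. Of the fits without 1 library, that without naive replicate 2, the shallowest, gave the highest count in each. The comparisons of cell states changed by over 1.5 times only at 2-fold or more (769, 3335 and 3870 genes). Of the lists past camera, 1 of 13 in CD138+ and 3 of 12 in GL7+ cells with GSK-J4, 0 of 11 for the difference, 2 of 6 for CD138+ against GL7+ cells, and 3 of 14 and 4 of 15 against naive cells also passed with an estimated correlation. The correlation between fractions (0.51) was 0.56 with the stricter filter and 0.47 to 0.51 without 1 library, and that with the CD138+ against GL7+ difference (0.35) lay between 0.29 and 0.40 without 1 library.

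Over 232 results for named genes, 2506 alternative values held 2222 on the same side of the threshold, 278 that lost the call, 6 that gained it and 0 of opposite sign. For 71 called lists, 701 of 770 values stayed past the threshold and 69 did not. Beside the cases given with the results, the block ended the call of Slc30a1 in CD138+ cells (adjusted p = 0.1) and gave one to Spib in GL7+ cells (0.022), and it changed no other call of a gene or list in the text. Thinning all libraries to the depth of the shallowest left fewer calls, in the difference between fractions most of all. A DESeq2 fit and its size factors, foreseen for counts, were not run on RPKM.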

Other observations

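The summed reads of Mt1 and Mt2 and the values of other metal-regulated genes were tests chosen only after the result was seen. The change with GSK-J4 in GL7+ cells was also compared with that between CD138+ and naive cells under DMSO, which shares no library with it. Across 10866 genes, which are not independent replicates, Pearson r was 0.36 and Spearman 0.41, with a covariance of 0.0984. Simulated unchanged groups gave a mean r of 0.00, again set in advance by drawing each library independently, though these comparisons share mice. Of 631 genes that rose with GSK-J4 in GL7+ cells 506 were higher in CD138+ than in naive cells (252 for independent lists), and of 838 that fell 606 were lower (364 for independent lists). The change in CD138+ cells had r = 0.04 with the difference between GL7+ and naive cells, where again no library is shared. Of 501 genes that rose with GSK-J4 in CD138+ cells 271 were higher in GL7+ than in naive cells (207 for independent lists), and of 936 that fell 451 were lower (378). In naive cells, summed marker levels were 131 ± 25.4 RPKM for the myeloid list and 217 ± 13.2 for the erythroid and platelet list (n = 3), against 6.4 to 12.4 and 1.64 to 9.39 as group means of the cultured cells.

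Mt1 and Mt2 had the largest changes with GSK-J4 in both fractions. Genes of 400 to 1200 bases near their level had a median log2 change of -0.09 in CD138+ cells (226 genes, 5th to 95th percentile -0.50 to 0.32), which argues against short length as the cause. The reads of both genes summed rose 18.5-fold in CD138+ cells, from 10.5 ± 1.04 to 194 ± 15.3 CPM (n = 3), and stood at 5.0 ± 0.744 and 80.6 ± 4.11 in GL7+ cells. Reads moving between the paralogs could not raise both genes. Since each had risen, the sum was bound to rise and adds no support of its own. A response of metal-regulated genes at large, a hypothesis that the iron-binding chemistry of such inhibitors may raise, predicted a rise of Slc30a1, a zinc exporter, and Tfrc, the transferrin receptor, in both fractions. Their lowest log2 change was 0.19 (Tfrc in CD138+ cells, SE 0.07, adjusted p = 0.073, against 0.34 and adjusted p = 0.004 in GL7+ cells), under the bound of 0.20 by less than its SE, so that explanation and its absence cannot be told apart here; Slc30a1 stood at 0.40 in CD138+ (adjusted p = 0.039) and 0.39 in GL7+ cells (0.045), calls that were lost with a pseudocount of 0.1 in GL7+ cells (0.051), without any 1 GL7+ library and without any 1 CD138+ library except DMSO replicate 1.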
